A study of Homo sapiens with 15 samples.

How the data were processed

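The data are percent CpG methylation values of repetitive elements in 15 bisulfite sequencing libraries of the colorectal carcinoma cell lines DLD1, HCT116 and HCT8. Per the labels' protocols, DNA was extracted, bisulfite converted with a Zymo Research lightning kit, made into libraries with the EpiGnome kit and sequenced on a MiSeq with paired reads of 75 bp. The labels also give the molecule as total RNA and the source as transcriptomic, which the protocols contradict; the values were treated as DNA methylation.

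The submitters' processing notes name BSMAP 2.74, a bisulfite read aligner, Picard 1.8.4, a toolkit for alignment files, and the genome build hg19, without saying how each was used. Per the file headers, the authors deposited the percent CpG methylation of repeats annotated in RepeatMasker, with a column per library. The percent values were rounded to whole numbers. How CpGs or reads were combined per repeat, any coverage filter and the number of reads per value are not given in the sources used here. No normalization between libraries is stated. The table has 835 rows; 1 row (0.12%) carries no repeat name and was left out, leaving 834.

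Libraries were grouped by line and dose from their titles, and every column name equals a sample title. Because the replicates at 0 and 1000 nM are technical, they were averaged within line and dose, and the 3 lines were the unit of replication for the dose comparisons. p-values from separate libraries measure only technical spread. Overall levels were the unweighted mean of the 834 repeats per library; they do not depend on the order of the rows as long as each column covers the same repeats. They were compared by exact sign flips over lines and, as a test added after the data were seen, by exact permutation of dose labels within lines. The response of each line was compared with that of the other lines by an exact permutation over 6 replicate differences. They were formed by replicate number, for which the labels give no shared batch, and the other ways of pairing the libraries within lines were tried after the data were seen.

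Row-by-row tests used limma 3.58.1 in R 4.3.3 on percentage points, with line as a covariate on 9 line-and-dose means, and a second limma fit with 9 groups on the 15 libraries for comparisons within and between lines. Rows were called at a Benjamini-Hochberg adjusted p of 0.05. In simulated data with noise of 16.7 points, 200 of 834 rows moved by 20 points were recovered at 2% and rows moved by 40 points at 89% in the 1000 nM against 0 nM comparison across lines, with a false share of 0.559% at 40 points. Within DLD1 the fit on the 15 libraries recovered 0.5% at 20 points and 24.5% at 40 points. Every simulated library had the same starting level in a row, unlike the libraries of the table. The noise was taken from the table and includes the disagreement between its rows.

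The agreement of rows between libraries was checked by Pearson correlation across repeats with 10000 row shuffles, and the agreement of values with names by the variance explained by 19 lists of repeats with 100000 shuffles per library. These checks were added after the data were seen. The lists (satellites, young, older primate and mammalian L1, L2 and CR1, AluY, AluS, AluJ, MIR, SVA, HERV-K, HERV-H, HERV-W, HERV-9 and LTR12, HERV-L and ERVL, MaLR, other HERV and LTR, DNA transposons, RNA genes) were fixed by name patterns before the data were examined and cover 507 repeats. The table has no class column, so names starting with MER were left out of the lists. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. In the single library in which list membership passed adjustment, lists were described by their percentile among 10000 random lists of the same size drawn from its repeats.

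The rule for named repeats, also fixed beforehand, was to name the 10 largest decreases and increases among called rows per dose, the 5 largest differences each way between untreated lines, the 5 smallest interaction p-values, 14 fixed repeats and the largest changes of each list. Its parts that rest on changes were not applied, because rows could not be followed between libraries; the exception is the single row called between untreated lines. Of the 14 fixed repeats 13 were measured, and SST1 had no row of its own. Other repeats are named as examples from their list, chosen after their values were seen.

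Alternatives fixed beforehand were other handling of technical replicates, a block for the replicate number, weights, a logit scale with an offset of 1 point, a variance trend with robust estimation, centring on library medians, a minimum level of 20%, and leaving out lines and libraries. Coverage minimums and coverage weights could not be applied without coverage. No genome was used, so no coordinates are given. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.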

Results

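DNA methylation of repetitive elements was measured by bisulfite sequencing in 3 human colorectal carcinoma cell lines, DLD1, HCT116 and HCT8, cultured with 0, 500 or 1000 nM 5-azacitidine. 5-Azacitidine is a cytidine analogue that is built into nucleic acids and traps DNA methyltransferases, so that methylation is lost as cells divide. Each line had 5 libraries: 2 technical replicates without drug, 1 library at 500 nM and 2 technical replicates at 1000 nM. The deposited values were the percentage of methylated CpGs for each of 834 named repeats of the RepeatMasker annotation, as whole percents. The depth behind each value is unknown, so no counting interval can be given. The share of repeats listed at exactly 0% or 100% ranged from 1.44% in replicate 1 of HCT116 at 0 nM and at 1000 nM to 17.9% in the HCT8 library at 500 nM.

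The first comparison asked whether the drug lowered methylation of repeats as a whole. In DLD1 the mean over repeats was 60.3% ± 0.20 (SD, n = 2 technical replicates) without drug, 37.0% at 500 nM (1 library) and 37.6% ± 1.00 (n = 2) at 1000 nM. In HCT8 it was 68.3% ± 0.456 (n = 2), 44.6% (1 library) and 47.6% ± 1.55 (n = 2). In HCT116 it was 72.9% ± 0.00424 (n = 2), 54.7% (1 library) and 59.7% ± 3.97 (n = 2). The mean of every treated library lay below those of both untreated libraries of its own line. Relative to the untreated level, 1000 nM went with a loss of 37.6% in DLD1, 30.3% in HCT8 and 18.1% in HCT116.

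Over the 3 lines the mean difference between 1000 nM and no drug was -18.9 percentage points with an SD over lines of 5.03 (n = 3 lines). For 500 nM it was -21.7 points with an SD of 3.06 (n = 3 lines). Both were negative in 3 of 3 lines, and the two-sided exact sign-flip p was 0.25 for each, the smallest that 3 lines can give. An exact permutation of the dose labels within lines over the libraries gave a two-sided p of 0.00926 for 1000 nM (216 arrangements) and 0.037 for 500 nM (27 arrangements), the smallest values these designs allow. That test was added after the data had been seen, and because the replicates are technical it measures the spread between libraries and not between cultures.

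**Figure D1:**
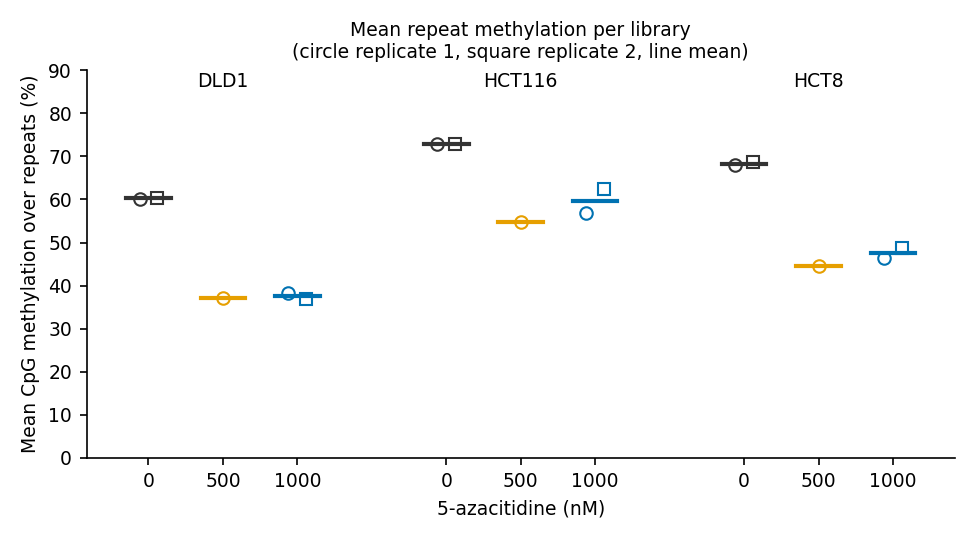
Mean CpG methylation over 834 repeats (y axis, percent) for each of the 15 libraries, by cell line and 5-azacitidine dose (x axis, nM). Circles are replicate 1, squares replicate 2 and horizontal lines group means; the treated groups lie between 37.0% and 59.7%, and the untreated groups of the same lines between 60.3% and 72.9%.

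The lower level at 1000 nM that a graded response would give was not seen in the means over replicates. The mean at 1000 nM exceeded that at 500 nM by 0.544 points in DLD1, 3.04 points in HCT8 and 5.06 points in HCT116, a mean of 2.88 points with an SD over lines of 2.26 (n = 3 lines). This difference did not pass a test: the exact permutation within lines gave p = 0.185 (two-sided, 27 arrangements), and the exact sign-flip p was 0.25. The 500 nM libraries also held the most repeats listed at 0% of any library of their line, 64 in DLD1, 25 in HCT116 and 90 in HCT8. The order in DLD1 rested on 1 library: replicate 1 at 1000 nM was at 38.3% and replicate 2 at 36.9%, on either side of the 37.0% at 500 nM. In HCT116 the replicates at 1000 nM were at 56.9% and 62.5% against 54.7% at 500 nM, and in HCT8 at 46.5% and 48.7% against 44.6%. Without replicate 2 of HCT116 at 1000 nM the mean difference over lines was 1.95 points, and without replicate 1 it was 3.82 points.

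The whole distribution was shifted at 1000 nM, not only its lower end. In DLD1 the 10th percentile over repeats was 40% without drug and 16.5% at 1000 nM, and the 90th percentile was 76.8% and 56.5%. In HCT8 the 10th percentile was 51.1% and 29.5%, and the 90th percentile 84.0% and 64.5%. In HCT116 the 10th percentile was 55.6% and 40.3%, and the 90th percentile 88.5% and 79.0%. The upper end was less clear in HCT116, where the 90th percentile was 88.0% in replicate 2 at 1000 nM and 84.0% in untreated replicate 1. The HCT8 library at 500 nM was the widest, with a 10th percentile of 0.0% and a 90th percentile of 78.0%. These percentiles describe each library's own ranking of repeats and do not follow single repeats from dose to dose.

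**Figure D2:**
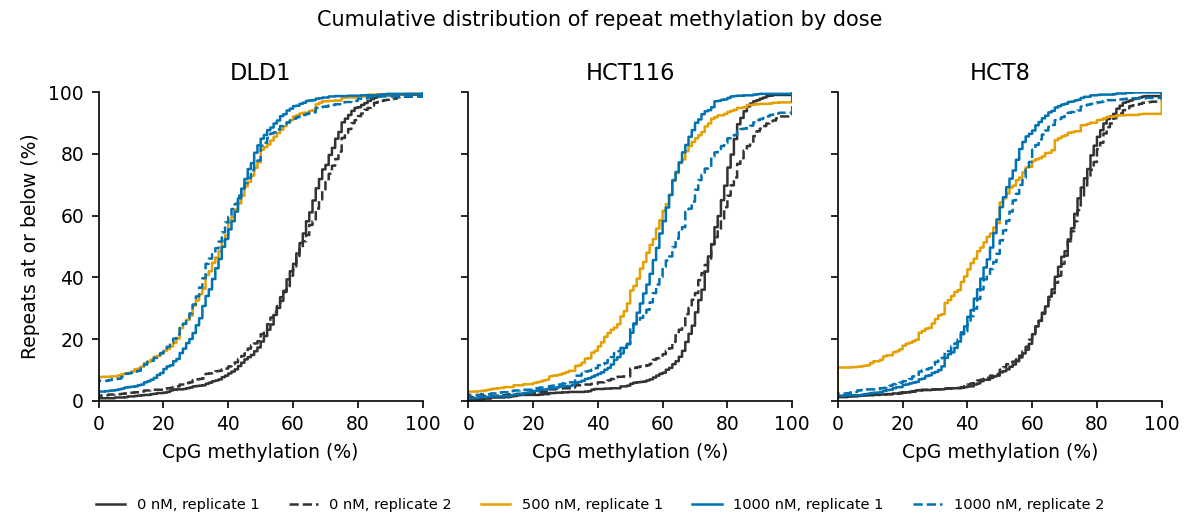
Cumulative share of repeats (y axis, percent) at or below each CpG methylation level (x axis, percent), with a panel per cell line, colours for dose, solid lines for replicate 1 and dashed lines for replicate 2. The curves at 500 and 1000 nM lie to the left of the untreated curves over most of the range; the HCT8 curve at 500 nM starts at 10.8% of repeats at 0% and crosses the untreated curves near its upper end.

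Among untreated libraries the mean of DLD1 minus that of HCT116 was -12.6 points and DLD1 minus HCT8 -8.07 points, and the mean of HCT116 was 4.54 points above that of HCT8. The replicates are technical, so the spread between cultures of a line is unknown, and with 2 libraries per line an exact permutation test cannot go below p = 0.333. Whether the lines differ is therefore left open. DLD1 and HCT8 are reported in cell line catalogues to come from the same donor, so the 3 lines may not be independent.

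The response to 1000 nM was smallest in HCT116. Its replicates gave differences of -15.96 and -10.4 points, against -21.8 and -23.5 points in DLD1 and -21.5 and -20.0 points in HCT8. The HCT116 difference was 8.55 points smaller than the mean of the other lines, with an exact permutation p of 0.0667 (two-sided), the smallest that the 15 splits of 6 replicate differences allow. The same permutation test gave p = 0.133 for DLD1 and p = 0.733 for HCT8. The p for HCT116 is not adjusted for picking the line with the smallest response. The differences were formed by replicate number, which the labels tie to nothing shared. All 8 ways of pairing the untreated and treated libraries within lines gave the same p. Pairing cannot change the mean difference of a line, so this is no separate support. As the replicates are technical, this p measures the spread between libraries and not between cultures. The replicates of HCT116 at 1000 nM were 5.61 points apart, and replicate 2 held 56 repeats at 100% against 5 in replicate 1. Untreated HCT116 showed the same, with 66 repeats at 100% in replicate 2 against 8 in replicate 1, but its means were 0.006 points apart. Without values of 0% and 100% the replicates at 1000 nM were at 57.1% and 61.1%.

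Values of a named repeat could not be compared between libraries in this table. Across the 834 repeats, the 6 pairs of technical replicates had Pearson correlations from -0.0477 to 0.0843, with a mean of 0.00212 and a one-sided permutation p of 0.436 (10000 shuffles of the rows). Over all 105 pairs of libraries the highest correlation was 0.0843. Repeats are not independent replicates, so these values describe the table. AluY, a high-copy family, was listed at 0% and 77% in the 2 untreated HCT116 replicates and at 95% and 57% in those of HCT8. The large-subunit ribosomal RNA repeat LSU-rRNA_Hsa was listed at 5% and 83% in the untreated DLD1 replicates.

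Whether values followed the names was then tested within each library, by the share of variance across 507 repeats that membership of 19 repeat lists explained. In replicate 1 of untreated DLD1 the lists explained 34.2% of the variance, against a mean of 3.55% in shuffled rows (permutation p = 1e-05, the smallest that 100000 shuffles can give, Benjamini-Hochberg adjusted p = 0.00015 over 15 libraries). In the other 14 libraries they explained 1.87% to 7.86%, and none passed after adjustment. The highest of these was replicate 1 of untreated HCT116 (permutation p = 0.00975, adjusted p = 0.0731). Across repeats it correlated at 0.00524 with replicate 1 of untreated DLD1, and its SD over the AluS names was 9.79 points. These values argue against this library following the names as replicate 1 of untreated DLD1 did. A weaker tie to the lists stays open. The SD over the 17 AluS names was 1.63 points in replicate 1 of untreated DLD1 and 7.81 to 25.01 points in the others.

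**Figure D3:**
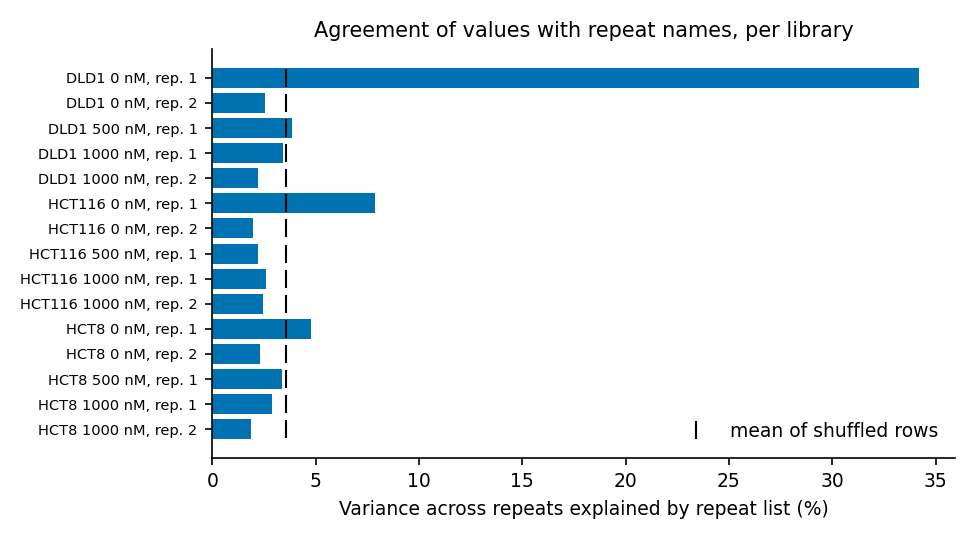
Share of the variance across repeats explained by membership of 19 repeat lists (x axis, percent) in each of the 15 libraries (y axis); vertical ticks mark the mean of shuffled rows. Replicate 1 of untreated DLD1 stands at 34.2%, and the other libraries lie between 1.87% and 7.86%.

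Named repeats are therefore described in replicate 1 of untreated DLD1 alone, a single library with no replicate check and a median of 62.0%. SVA elements, composite hominoid retrotransposons, were the most methylated list (mean 82.7% ± 3.78, SD over 6 members), with SVA_E at 88% and SVA_F at 85%. The Alu lists came next: AluY averaged 75.4% ± 4.11 (14 members), AluJ 74.3% ± 0.951 (7 members) and AluS 72.8% ± 1.63 (17 members), and every member of the 3 lists lay above the library median. Within AluY, members ranged from 67% for AluYk12 and 70% for AluYa8 to 79% for AluYb8 and 83% for AluYb9, with AluY itself at 73%. DNA transposons averaged 69.5% ± 9.25, with 43 of 55 members above the median. The means of SVA, AluY and DNA transposons exceeded those of all 10000 random lists of the same size.

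Of the LINE-1 elements, the autonomous retrotransposons of the human genome, the young and older primate lists stood lower. Young L1 averaged 53.3% ± 3.24 and older primate L1 51.8% ± 4.75, and all 9 and all 17 members lay below the library median. L1HS, the human-specific family that is still mobile, was at 59% and L1PA2 at 55%. Older primate L1 lay at the 1.59th percentile of random lists of its size and young L1 at the 9.38th. Mammalian L1 averaged 60.5% ± 10.1 over 76 members, with 36 above and 36 below the median, and lay at the 59.5th percentile. The ancient L2 and CR1 list (65.4% ± 1.72, 7 members) and MIR (65.2% ± 0.957, 4 members) were narrow and slightly above the median.

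Satellites, the tandem repeats of centromeric and other heterochromatin, averaged 43.8% ± 15.4, with 10 of 12 members below the median and a mean at the 0.07th percentile of random lists. HSATII was at 56%, the centromeric ALR/Alpha at 49%, GSATII at 44%, BSR/Beta at 23% and CER at 17%, while TAR1 reached 68% and SATR1 67%. RNA gene repeats had the lowest mean, 36.1% ± 34.7 over 24 members, below all 10000 random lists. LSU-rRNA_Hsa and the spliceosomal U1 were at 5%, 5S at 8% and U4 at 9%, whereas U6 was at 78%; 3 tRNA names were at 0% and 3 at 100%.

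Lists of endogenous retroviruses and their long terminal repeats lay on either side of the library median. HERV-K averaged 62.8% ± 9.66 (6 of 12 members above the median), with HERVK-int at 66%, LTR5_Hs at 65% and LTR5 at 81%. HERV-H averaged 68.2% ± 8.04 (5 members), with HERVH-int and LTR7 both at 62%. The HERV-9 and LTR12 list averaged 67.1% ± 8.63 (8 members), from 54% for HERV9-int to 79% for LTR12C. HERV-W averaged 70.5% ± 4.95 (2 members), with HERV17-int at 67%. HERV-L and ERVL averaged 57.2% ± 7.10, with 26 of 37 members below the median, and MaLR 57.4% ± 9.87, with 41 of 64 below. The other HERV and LTR names averaged 61.0% ± 11.1, with 63 above and 62 below among 131 members.

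**Figure D4:**
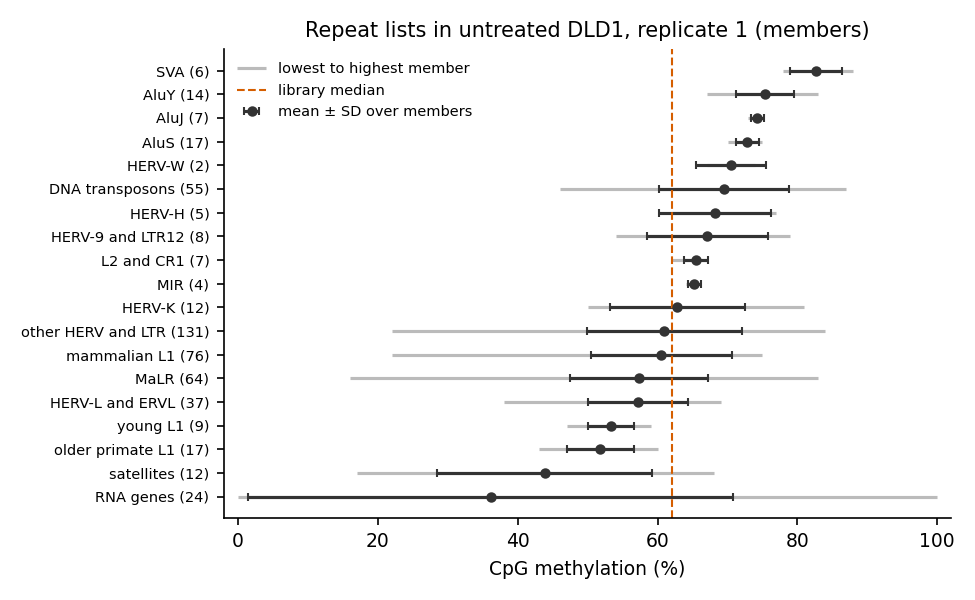
CpG methylation (x axis, percent) of 19 repeat lists (y axis, number of members in parentheses) in replicate 1 of untreated DLD1. Points and black bars are mean ± SD over members, grey lines run from the lowest to the highest member, and the dashed line is the library median of 62.0%; SVA and Alu lie above it and satellites and RNA genes have the lowest means.

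The row-by-row tests fixed before the data were examined were run on the table as deposited, and their counts are counts of rows, not of repeats. With limma and Benjamini-Hochberg adjustment on 9 line-and-dose means, 0 of 834 rows passed at 1000 nM against no drug (197 rows at an unadjusted p under 0.05) and 115 rows passed at 500 nM against no drug, all lower with drug. For 1000 nM against 500 nM 0 rows passed (62 unadjusted). When the rows of every library were shuffled at random 100 times, the same tests gave 0 to 1, 12 to 182 and 0 to 2 rows, and 46 of the 100 shuffles gave at least 115 rows at 500 nM. The counts depended on the fit. At 1000 nM against no drug, 179 rows passed with all libraries as separate values, 146 with a block for the replicate number, 21 with the group as a random block and 1 with weights. At 500 nM the 115 rows became 231 with all libraries as separate values, 1 on the logit scale and 0 after centring on library medians. They became 32, 49 and 24 without DLD1, HCT116 and HCT8, and 76, 23 and 69 without replicate 1 at 1000 nM of DLD1, HCT116 and HCT8. For 1000 nM against 500 nM, 2 rows passed without replicate 2 of DLD1 at 1000 nM.

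Within lines, limma on the 15 libraries called 0 rows at 1000 nM in DLD1 (252 unadjusted), HCT116 (107 unadjusted) and HCT8 (191 unadjusted). In simulated data this fit recovered 0.5% of rows moved by 20 points and 24.5% of rows moved by 40 points within DLD1. Recovery within HCT116 and HCT8 was not read. The simulated rows held the same repeat in every library, which was not shown for this table, and their noise includes its disagreement between rows. The simulation therefore cannot say which changes these counts of 0 exclude. Without replicate 1 at 1000 nM of the same line, 13 rows passed in HCT116 and 6 in HCT8; in DLD1 1 row passed without either replicate of HCT116 at 1000 nM. The test of a difference in response between lines called 0 rows (44 unadjusted in the joint test, and 64, 40 and 32 for DLD1 against HCT116, DLD1 against HCT8 and HCT116 against HCT8). Between untreated lines it called 0 rows for DLD1 against HCT116 (97 unadjusted) and DLD1 against HCT8 (63 unadjusted) and 1 row, named L1P3, for HCT116 against HCT8 (limma adjusted p = 0.0117), where shuffled rows gave 0 to 4 and 23 of 100 shuffles at least 1. The call was lost with the replicate block, on the logit scale, with the variance trend and robust estimation, and without replicate 1 of untreated HCT116 or replicate 2 of untreated HCT8, and without replicate 1 of untreated HCT8 2 rows passed. For DLD1 against HCT116, 12 rows passed without replicate 1 of untreated DLD1. In the row named L1P3 HCT116 was listed at 4% and 25% and HCT8 at 88% and 100%. No row is read as a result for the repeat that names it.

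The 19 lists could not be compared between doses either, because in 14 of the 15 libraries values were not shown to follow the lists. The planned set tests were run on the rows as deposited. The mean differences of the rows so named at 1000 nM lay between -23.4 and -16.1 points. At 500 nM they lay between -38.2 points for the 2 rows named HERV-W and -14.5 points for the 24 rows named RNA genes, against -21.7 points over all rows. All were of the sign of the library means. The camera set test called 0 of 19 lists at either dose, with smallest adjusted p of 0.581 at 1000 nM and 0.283 at 500 nM, and of 0.859 and 0.900 with an estimated correlation. The correlation across rows between the untreated level and the difference at 1000 nM was -0.676 (Spearman's rho -0.635), and shuffled rows gave -0.733 to -0.658. With the untreated level from replicate 1 and the difference from replicate 2 it was 0.0132 (rho 0.0443). Libraries did not correlate across rows, so this low value was fixed beforehand and does not bear on the repeats.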

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

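The lower overall level with drug kept its sign in every fit of library means, and moved by less than its SD over lines. Without replicate 1 or 2 in turn it ranged from -19.8 to -17.9 points at 1000 nM and from -21.8 to -21.6 points at 500 nM, and the difference of 1000 minus 500 nM from 1.95 to 3.82 points, both extremes from leaving out a replicate of HCT116 at 1000 nM. The counts of rows were less stable. At 1000 nM against 0 nM, 0 rows became 179 with all libraries as separate values, 146 with the replicate block, 21 with the group as a random block and 1 with weights. At 500 nM against 0 nM, 115 rows became 231 with all libraries, 1 on the logit scale, 0 after centring on library medians, and 32, 49 and 24 without DLD1, HCT116 and HCT8; leaving out single libraries gave 23 to 129, with the lowest count without replicate 1 of HCT116 at 1000 nM. At 1000 nM against 500 nM, 0 rows became 3 with all libraries, 2 with weights, 1 on the logit scale, 1 with the variance trend, 1 after centring and 5 without DLD1, and 0 to 2 without single libraries. Within DLD1, 0 rows became 2 on the logit scale. Leaving out single libraries gave 0 to 1 rows in DLD1, 0 to 13 in HCT116 (13 without its replicate 1 at 1000 nM), 0 to 6 in HCT8 (6 without its replicate 1 at 1000 nM), 0 to 12 for untreated DLD1 against HCT116 (12 without replicate 1 of DLD1) and 0 to 2 for untreated HCT116 against HCT8. That last count of 1 was 0 with the replicate block, on the logit scale, with the variance trend, and without replicate 1 of HCT116 or replicate 2 of HCT8. Fry, which asks whether a list moves at all and not whether it differs from other repeats, called 18 of 19 lists at 500 nM and 18 at 1000 nM, and camera 1 list, RNA genes, at 500 nM without HCT116 (adjusted p = 0.0398, and adjusted p = 0.925 with an estimated correlation). As values were not shown to follow the lists in 14 libraries, none of these is a result for a list. The correlation of untreated level and difference turned from -0.676 to 0.0132 when the 2 came from different untreated libraries, which removes their shared error. As libraries of this table did not correlate across rows, that low value was fixed beforehand. It does not show whether the response depends on the untreated level. The cause of the other moves was not tested. The 20% minimum removed no repeat, so it tests nothing, and coverage settings were not run. The labels tie the replicate numbers to no shared batch or day. Deviations of same-numbered libraries correlated at 0.0443 in DLD1, -0.0232 in HCT116 and 0.0329 in HCT8. As no libraries of this table correlated across rows, this check cannot show whether the numbers pair the libraries. In every line at 0 and at 1000 nM, replicate 2 had the larger SD over repeats and the larger share at 0% or 100%. What the same-numbered libraries share is not given. All counts concern rows whose values could not be tied to a repeat across libraries, and the unknown depth limits every single value.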

Other observations

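The tests in this part were chosen after the results were seen. In replicate 1 of untreated DLD1, the 73 simple repeats outside the lists were compared by their unit. The 15 with CG in the repeated unit averaged 38.0% ± 29.97 (SD over repeats), with 11 below 50%, and the 58 without averaged 56.5% ± 20.3, with 18 below 50%. (CGG)n was at 16%, (CG)n at 24% and (CCG)n at 27%, and the GC_rich low-complexity class at 28%, whereas (CA)n and (TG)n were both at 72%. (CA)n and (TG)n are the same sequence on opposite strands. A repeated unit without CG holds no CpG, so the values of those 58 names come from CpGs that the listed unit does not hold. The comparison therefore sets CpGs of different origin against each other. Both groups held exceptions: among units with CG, (TCCGG)n was at 100% and (CGTG)n at 82%, and among those without, (AAGTG)n was at 0% and (CTGGGG)n at 12%. The mean of the CG group lay at the 0.31st percentile of 10000 random lists of simple repeats, and at the 0.45th when (CATTC)n at 44% and (GAATG)n at 34%, which belong to the satellite list and have no CG in the unit, were added. This is consistent with the hypothesis that CpG-dense simple repeats were less methylated in this library. The units are not matched for copy number or depth, and 1 library was read. Some names hold the same sequence on opposite strands, such as (CCG)n and (CGG)n or (CACG)n and (CGTG)n. The random lists drew single names as if they were separate, so the percentiles may be too extreme.

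Technical replicates of this table did not correlate across repeats. Few reads per repeat, in values that follow the names, would leave the high-copy names closest between replicates. The SD of the replicate difference in 19 names of the Alu, MIR and L2 families was 0.78 to 1.25 times that in the rest. The SD over the 17 AluS names was 1.63 points in replicate 1 of untreated DLD1 and 7.81 to 25.01 points in the other libraries. If values follow the names, these values argue against few reads as the only cause for these high-copy names. If they do not, the 19 names need not hold high-copy repeats, and the ratios say nothing about depth. The depth of a name is not given, so a part of low depth stays open. Exchanged library columns would leave some pair correlated, and the highest of 105 correlations was 0.0843. Another candidate explanation is that the values of most columns stand in another row order than the names: only 1 of 15 libraries, the leftmost column, had values that followed the repeat lists after adjustment. No order was reconstructed, and no biological explanation was tested.

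The smaller response of HCT116 at 1000 nM has several open explanations. With each treated replicate set against the mean of both untreated libraries of its line, replicate 1 of HCT116 at 1000 nM was at -15.96 points, still short of the -23.4 to -19.6 points of the replicates of DLD1 and HCT8, but by less than the 5.61 points between the HCT116 replicates, so replicate 2 cannot be excluded as the source. In log2 odds, which allows for the higher untreated level of HCT116, its replicates were at -1.02 and -0.69 against -1.38 to -1.18 in the other lines, again a gap below its own replicate gap. At 500 nM HCT116 also had the smallest difference, -18.2 points against -23.2 in DLD1 and -23.8 in HCT8, but both doses are set against the same untreated libraries, so the 2 differences are not independent. A difference between the lines themselves remains possible and untested beyond these libraries.

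The lower mean at 500 nM than at 1000 nM may come in part from repeats listed at 0% in the 500 nM libraries. Without values of 0% and 100% the difference over lines was 1.94 points with an SD of 2.67 (n = 3 lines), against 2.88 points with them, and in DLD1 it was -0.937 points. With 1 library per line at 500 nM, the dose and these libraries cannot be told apart.

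The 3 counts of rows in the dose comparisons were set against the other splits of the 6 line means. At 500 nM against 0 nM 115 rows passed and the highest of the other splits gave 0, so 1 of 10 splits reached that count. Among the 4 splits that, like the real one, part the 2 means of every line, the highest of the other 3 gave 0 as well. Only the real split sets all treated means against all untreated means, so it alone carries the lower library means in full. With shuffled rows 46 of 100 shuffles gave at least 115 rows, and after centring on library medians 0 rows passed. The count is therefore no result for single rows. At 1000 nM against 0 nM and against 500 nM 0 rows passed and the highest other was 0, so all 10 splits reached it by construction and nothing was tested. With 10 splits a share under 0.05 cannot be reached.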
